A study of Mus musculus with 10 samples.

How the data were processed

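RNA from the liver of 10 ApoE-/- mice was measured on Affymetrix 430 2.0 arrays with a biotin label, 1 mouse per array, per the labels. Of these mice, 5 had received an adenovirus that expresses GFP (control, replicates 11 to 15) and 5 an adenovirus that expresses a dominant negative form of cJun (labelled dn-cJun, replicates 16 to 20). GFP is a fluorescent protein that serves here as the control cargo. The replicate numbers come from the sample titles, do not repeat between the groups and pair no arrays. Per the labels' protocols, RNA of control 11 was extracted with Trizol, and the entry of the other 9 arrays names only Affymetrix.

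The deposited values are probe set intensity on a linear scale. The software that made them is not given in the sources used here. In each column, 100% of the values were whole multiples of a single step per array, within a tolerance of 0.02 steps. In units of that step the mean after trimming 2% at each end was 500.003 to 500.004 on every array, and the columns then carry a further factor per array between 0.887 (dn-cJun 17) and 1.22 (control 11), with a factor of 1 for control 13. The purpose of that factor is not stated. Detection calls were not used here.

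The values were taken as log2(intensity + 16). The array medians on that scale spanned 0.50, above the limit of 0.1 fixed before the data were examined, so quantile normalization was applied (limma 3.58.1 in R 4.3.3). Fold changes are on the log2(intensity + 16) scale and understate the changes of dim genes. Of 45101 probe sets, 64 were controls and were left out after normalization, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 are unnamed here. Entrez identifiers matched 99.4% of the single-gene annotation entries to the mouse gene table of assembly GRCm38.p6, which changed no symbol; that table was otherwise used only for older names of list members and for which genes neighbour each other. The probe sets with 1 symbol stood for 18193 genes. Each gene was represented by its probe set with the highest mean, and genes below the 40th percentile of all probe sets were left out, which left 12736 genes. Of the 45 named genes, 15 had further probe sets above that filter, 26 in all, and 6 of these had the opposite sign.

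Groups were compared as arrays labelled dn-cJun minus control with limma (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. In all, 28 gene lists were fixed beforehand, 6 on lipid metabolism and 22 on other pathways and cell types. The 27 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists. Member counts are given over all genes and adjusted over the list alone. RNA quality was read as the log2 difference between the 3 prime and 5 prime control probe sets of Gapdh and Actb, with a two-sided exact permutation test over 252 splits, adjusted over both genes. The number of arrays limits the precision.

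The genes named were chosen by a rule fixed before the data were examined. It takes Jun and Apoe, the 8 largest rises and the 8 largest falls among genes past the threshold whose group ranges do not overlap, up to 4 members past the threshold of each lipid list and up to 2 of each other list. Where no member of a list passed, it takes the member with the smallest p. Other list members given as examples, the neighbours of Apoe, the sex-linked genes and the genes in the last part of the closing section were chosen after their values were seen.

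The fit was tested on simulated data for the comparison of 5 against 5 arrays over 12736 genes, with 200 genes changed in each of 10 repeats. It recovered 37.1% of the genes changed by a log2 fold of 0.5, 76.5% of those changed by 1 and 94.4% of those changed by 2, with 4.29% false calls and no gene or list called in simulations without change. These simulations treat genes as independent.

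The alternatives planned were the values as deposited, equal array medians, a pseudocount of 1 or 64, no filter or the 60th percentile, the mean of a gene's probe sets, exclusion of probe sets whose names end in _x_at or _s_at, eBayes without trend or robust, array weights, each array left out in turn, every probe set as the unit, adjusted p thresholds of 0.01 and 0.1, a minimum log2 fold change of 1, camera with an estimated correlation, and fry. Added after seeing the data were the further factor per array undone, control arrays 14 and 15 left out (also with an estimated correlation), a term for these arrays, and an exact permutation test of a mean score per list and array. Figures were drawn with matplotlib.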

Results

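Gene expression was measured in the liver of 10 mice, 5 given a control adenovirus and 5 given an adenovirus with dominant negative cJun. cJun is a subunit of the AP-1 transcription factor, and the title of the study names lipid homeostasis as its subject. Per the labels each array holds a separate mouse. The median deposited intensity of an array lay between 85.1 and 127.1, and the arrays correlated at 0.944 to 0.965 over all probe sets on the log2 scale.

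Apoe, the gene the labels describe as lost in all 10 mice, had the largest log2 fold change of all genes tested. Its log2 signal was 10.25 ± 0.59 (SD, n = 5) in the control arrays and 15.66 ± 0.21 (SD, n = 5) in the arrays labelled dn-cJun. The log2 fold change was 5.41 with a standard error of 0.22, a 42.6-fold higher signal (limma adjusted p = 2.57e-08). The ranges were 9.42 to 10.94 and 15.31 to 15.82. On the arrays labelled dn-cJun, Apoe stood at the 99.96th percentile of all probe sets, and on the control arrays at the 87.66th. A signal at that level goes against the ApoE-/- label of these 5 mice, unless the probe set reads a part of the transcript that the mutation leaves in place. Its position in the gene is not given in the sources used here. The arrays are therefore called "labelled dn-cJun" throughout, and every direction below depends on groups that also differ in Apoe signal. Apoc1 and Tomm40, which lie beside Apoe, had log2 differences of 0.08 (SE 0.07) and -0.04 (SE 0.10). Among the 20 nearest tested genes 1 passed the threshold, Clasrp, at 0.81 (SE 0.13, limma adjusted p = 0.0219).

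No difference in Jun, which encodes cJun, was detected between the groups. Its log2 signal was 10.43 ± 0.24 (SD, n = 5) in the control arrays and 10.37 ± 0.37 (SD, n = 5) in the arrays labelled dn-cJun, a log2 fold change of -0.07 with a standard error of 0.17 (limma adjusted p = 0.890). The second Jun probe set gave -0.11 with a standard error of 0.22. Whether either probe set lies in the part of the transcript carried by the virus is not given in the sources used here, so Jun does not check the virus label. No member of the AP-1 family list passed the threshold among 11 tested, by either adjustment (camera adjusted p = 0.709). Mafk had the smallest p of the list, with a log2 fold change of -0.50 (SE 0.20, limma adjusted p = 0.257), and -0.21 without controls 14 and 15.

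The sexes of the mice are not given in the labels, and the arrays differed in sex-linked transcripts. Xist, the RNA of the inactive X chromosome, had log2 signals of 13.71 in control 14 and 13.63 in control 15, against 5.90 to 6.72 in the other 3 controls and 5.96 to 6.63 in the arrays labelled dn-cJun. The Y-linked gene Eif2s3y was at 5.22 and 4.08 in controls 14 and 15 and between 10.58 and 11.13 in the other 8 arrays. Kdm5d and Uty, also on the Y chromosome, were low in the same 2 arrays. Counts are therefore also given without controls 14 and 15, an alternative chosen after seeing the data.

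**Figure D1:**
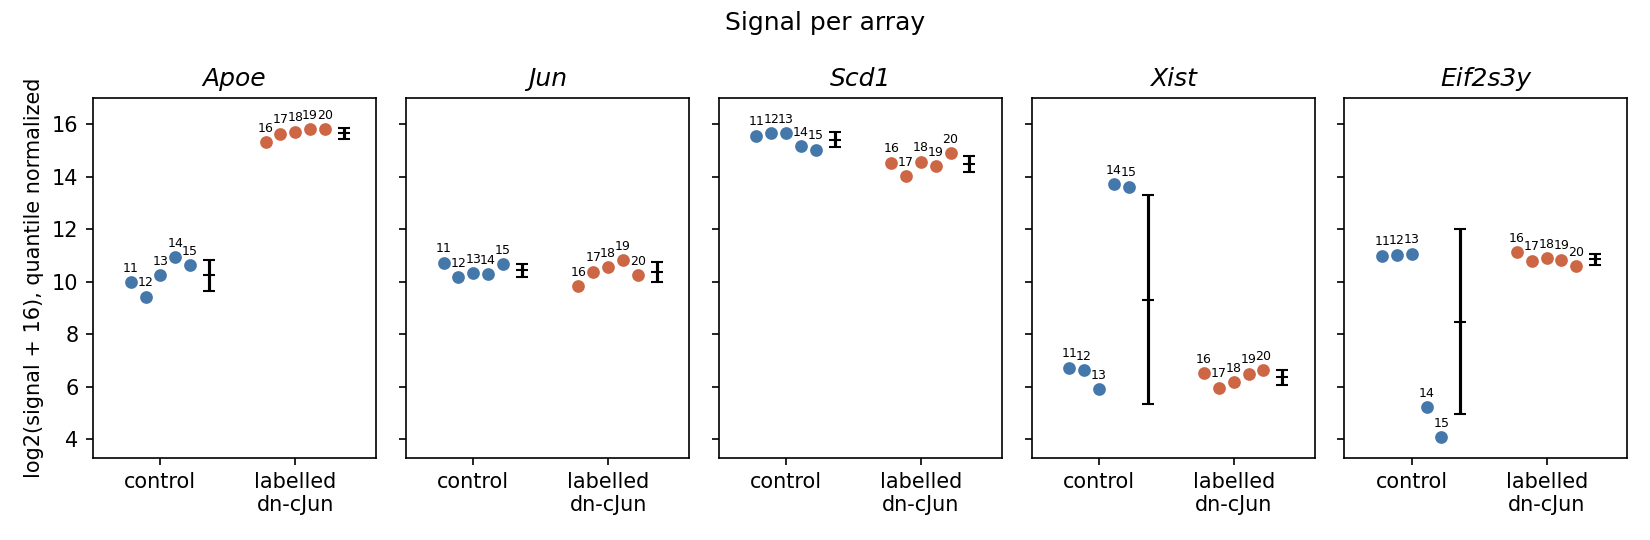
Log2 signal (y axis) of 5 genes on each array, numbered by replicate, for the control arrays and the arrays labelled dn-cJun; black marks show the mean and SD of each group (n = 5). Apoe lies above 15 on all arrays labelled dn-cJun and below 11 on all controls, Jun overlaps, and Xist and Eif2s3y separate controls 14 and 15 from the other arrays.

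Of 12736 genes tested, 44 were higher and 55 lower in the arrays labelled dn-cJun (limma, adjusted p under 0.05), and 1897 had an unadjusted p under 0.05. Without controls 14 and 15, 13 were higher and 39 lower among 12758 tested, and 32 genes were past the threshold in both fits. In the 67 genes that no longer passed, the log2 fold change without these controls was a median of 0.98 of its size over all arrays (quartiles 0.92 and 1.06) and the standard error 1.18 of its size. In 96 of the 99 genes the ranges of the groups did not overlap, which largely follows from their selection by a small p. Such separation was seen in 4.22% of all genes tested, where chance gives 0.794% on average. The difference between these shares was not tested. After Apoe, the largest rises were those of Cpne7 at 1.93 (SE 0.34, adjusted p = 0.0274), Ces5a, a carboxylesterase, at 1.82 (SE 0.35, adjusted p = 0.0323) and Rapgef3, an exchange factor activated by cyclic AMP, at 1.66 (SE 0.18, adjusted p = 0.00133). Mx2, an interferon-induced GTPase, rose by 1.41, Dnase1 by 1.36, Fbxo36 by 1.28 and Gadd45g, a stress-induced growth regulator, by 1.05 on the log2 scale. With 1 array left out, Rapgef3 kept its call in 10 of 10 fits, Fbxo36 in 8 and Mx2 in 7. Cpne7 and Dnase1 kept theirs in 4, Ces5a in 3 and Gadd45g in 2. A further Ces5a probe set gave 0.79, a further Fbxo36 probe set -0.35 and a further Rapgef3 probe set 0.23. Probe sets below the filter gave 0.11 for Cpne7, 0.55 for Ces5a and -0.015, 0.63 and -0.19 for Rapgef3. In the control arrays, Cpne7, Mx2 and Dnase1 stood at percentiles 29.34, 31.19 and 39 of all probe sets, below the level of the filter. They passed the filter, which uses the mean over all arrays, through the arrays labelled dn-cJun. Whether these genes were detected in the controls was not tested.

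The largest falls were those of Clec4e, a receptor of myeloid cells, at -1.40 (SE 0.29, adjusted p = 0.0426), Polh, a DNA polymerase, at -1.34 (SE 0.25, adjusted p = 0.0323) and Mmp13, a collagenase, at -1.29 (SE 0.22, adjusted p = 0.0232). Cd83, a marker of activated dendritic cells, fell by 1.26, Arrdc3 by 1.07, Bms1 by 1.05, Fabp5, a fatty acid binding protein, by 1.03 and Laptm5, a lysosomal membrane protein of blood cells, by 1.02 on the log2 scale. With 1 array left out, Arrdc3, Bms1 and Laptm5 kept their calls in 10 of 10 fits. Fabp5 kept its call in 6, Mmp13 in 4, Polh and Cd83 in 3 and Clec4e in 2. The further probe set of Fabp5 gave -1.08. That of Bms1 gave -0.08, and those of Laptm5 gave 0.03, -0.19 and 0.23, so the falls of these 2 genes rest on 1 probe set each. Polh and Clec4e had other probe sets only below the filter, at -0.26, -0.40 and -0.71 for Polh and -0.58 for Clec4e. The number of genes was unstable. It was 13 without dn-cJun 17 and 199 without control 12, it was 9 in eBayes without the intensity trend, and with the values as deposited, where the median gene shifted by -0.19, 22 genes were higher and 468 lower. With array medians made equal, 20 were higher and 45 lower.

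**Figure D2:**
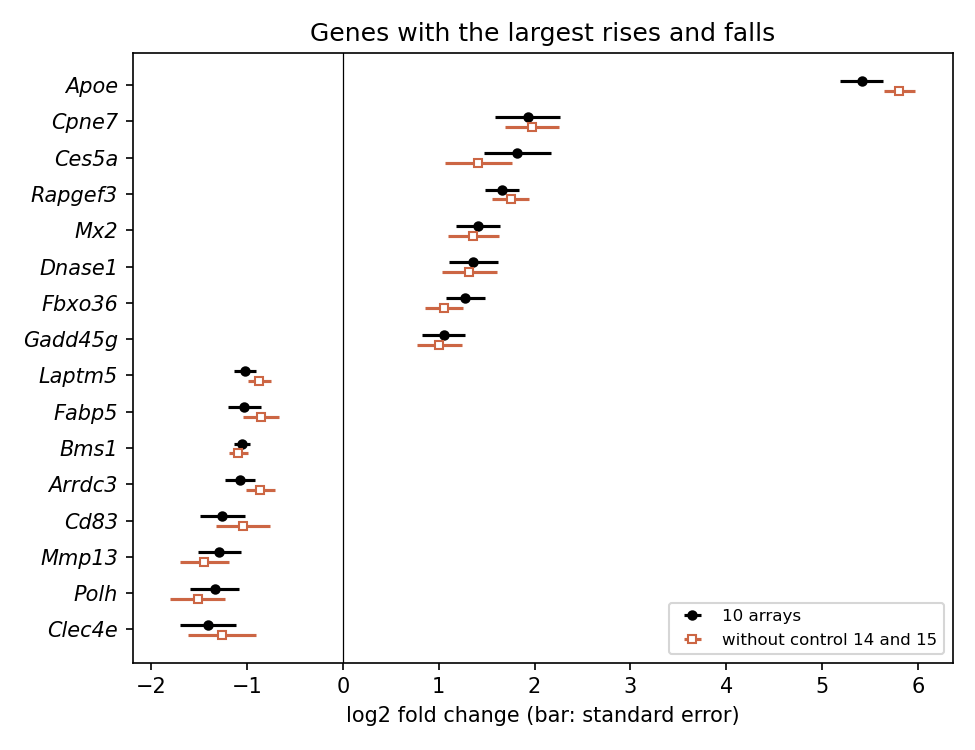
Log2 fold change (x axis, arrays labelled dn-cJun minus control, bars are standard errors) of the 8 genes with the largest rise and the 8 with the largest fall among genes past the threshold with separate group ranges, over 10 arrays (filled) and without controls 14 and 15 (open). Apoe stands apart at 5.41. Without these controls 8 of the 16 are no longer past the threshold (Ces5a, Mx2, Dnase1, Gadd45g, Clec4e, Polh, Cd83 and Fabp5).

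Genes of fatty acid and triglyceride synthesis did not pass as a list, but the member with the smallest p fell. Scd1, the desaturase that makes oleate from stearate, fell from 15.41 ± 0.30 (SD, n = 5) to 14.48 ± 0.32 (SD, n = 5), a log2 fold change of -0.93 with a standard error of 0.16 (limma adjusted p = 0.0228), and its further probe set gave -1.49. It was at -0.75 with equal array medians (limma adjusted p = 0.0676) and at -0.72 with the further factor per array undone (limma adjusted p = 0.0638), and it did not pass in eBayes without trend (limma adjusted p = 0.0924). It kept its call in 7 of 10 fits with 1 array left out and without controls 14 and 15 (-1.16, limma adjusted p = 0.00685). Scd1 was the only member of the 24 tested that passed over all genes. Adjusted over the list alone, 3 members were lower and 1 higher. Me1, which supplies NADPH for lipogenesis, was at -0.52 and Pnpla3 at -1.14, and Lpin1, a phosphatidate phosphatase, had the largest change of the list at 1.21. The list's median log2 fold change was -0.04 (camera adjusted p = 0.399). Without controls 14 and 15, 19 of 24 members were lower, and 2 members passed as lower over all genes. The list's median was then -0.15 and its camera adjusted p was 0.00368, and adjusted p = 0.802 with an estimated correlation.

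Genes of fatty acid oxidation and targets of PPARalpha, the nuclear receptor that induces this pathway, passed as higher at camera's preset correlation. Of 25 members tested, 17 were higher and 8 lower, with a median log2 fold change of 0.15 (camera adjusted p = 0.00546). With an estimated correlation the adjusted p was 0.873 (0.213 unadjusted). The mean of the members, each centred over the arrays, overlapped between the groups (exact permutation p = 0.468, unadjusted). It was -0.32 to 0.22 in the controls and -0.13 to 0.27 in the arrays labelled dn-cJun. No member passed over all genes, and 6 were higher adjusted over the list alone. Among them were the beta-oxidation enzymes Acaa2 at 0.24 (SE 0.06) and Acadm at 0.31 (SE 0.08), Cpt1a, which carries fatty acids into mitochondria, at 0.36 (SE 0.10), and Angptl4, an inhibitor of lipoprotein lipase, at 0.42 (SE 0.14). Without controls 14 and 15, 22 of 25 were higher and the median was 0.24 (camera adjusted p = 1.03e-06), and adjusted p = 0.574 with an estimated correlation.

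The other lipid lists did not pass. Cholesterol synthesis and SREBP2 targets had 10 members higher and 9 lower, a median of 0.0025 and no member past the threshold by either adjustment (camera adjusted p = 0.709, where camera's direction and the mean were lower). Hmgcs1, an early enzyme of the pathway, was at -0.29 (SE 0.08, limma adjusted p = 0.115). Lipoproteins, their receptors and sterol transport had 18 of 27 higher with a median of 0.02 (camera adjusted p = 0.504). Lpl, lipoprotein lipase, was at -0.52 (SE 0.13, limma adjusted p = 0.0935) and was the only member lower adjusted over the list alone. Under 3 other scalings this list passed as higher, at camera adjusted p = 0.00632 to 0.0242. With an estimated correlation and the main scaling its adjusted p was 0.873. Bile acid synthesis and transport had 14 of 23 higher with a median of 0.05 and no member past either adjustment (camera adjusted p = 0.577). Its member with the smallest p was Akr1d1, a steroid reductase of that pathway, at 0.26 (SE 0.07). For lipid droplets, fatty acid uptake and lipolysis the camera adjusted p was 0.709 over 20 members, with 3 higher and 2 lower adjusted over the list alone. G0s2, an inhibitor of lipolysis, was at 0.67 (SE 0.17, limma adjusted p = 0.0994), Plin4 at 1.14, Plin2 at -0.37 and Plin3 at -0.28. The last 3 encode lipid droplet coat proteins.

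Cell cycle genes had the smallest camera p of the lists. Of 29 members tested, 28 were lower, with a median log2 fold change of -0.35 (camera adjusted p = 1.2e-10). With an estimated correlation the adjusted p was 0.873, a value that adjustment gave to each of the 7 called lists. Unadjusted, camera with an estimated correlation gave p = 0.0608 for cell cycle and 0.213 to 0.399 for the other called lists. For cell cycle that p was 0.0303 without controls 14 and 15, and fry gave an unadjusted p of 0.0201 over all arrays. Ccnb2, a mitotic cyclin, was the only member past the threshold over all genes, at -0.71 (SE 0.13, limma adjusted p = 0.0323), and 10 were lower adjusted over the list alone. These included Mcm5 of the replicative helicase at -0.69, Cdc20 at -0.87 and Pcna at -0.43. Ccnb2 kept its call in 4 of 10 fits with 1 array left out. Without controls 14 and 15 all 29 were lower, with a median of -0.46, and Mcm5, Cdc20 and Pcna passed over all genes while Ccnb2 did not (limma adjusted p = 0.0508). The arrays of the control group differed in these genes. The mean of the members, each centred over the arrays, was 0.63 in control 11, the array whose extraction entry names Trizol, 0.25 and 0.09 in controls 12 and 13, -0.09 and 0.01 in controls 14 and 15, and between -0.33 and -0.07 in the arrays labelled dn-cJun. Without control 11 the camera adjusted p was 1.26e-07 and no member passed over all genes.

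Acute phase genes passed as lower at the preset correlation, with 19 of 25 lower and a median of -0.15 (camera adjusted p = 0.0110). With an estimated correlation the adjusted p was 0.873. Orm2, an orosomucoid, fell by 0.86 (SE 0.12, limma adjusted p = 0.0103), and 3 members, Orm1, Orm2 and Orm3, were lower adjusted over the list alone. The list's call was lost without controls 14 and 15 (median -0.02, camera adjusted p = 0.944) and under 3 other scalings (camera adjusted p = 0.843 as deposited, 0.820 with equal array medians and 0.973 with the further factor per array undone). Macrophage and Kupffer cell markers passed as lower at the preset correlation, with 13 of 18 lower and a median of -0.14 (camera adjusted p = 0.0123). With an estimated correlation the adjusted p was 0.873. Lyz2, lysozyme, fell by 0.70 (SE 0.13, limma adjusted p = 0.0294) and Cd5l, a protein secreted by macrophages, fell by 0.57 (SE 0.11, limma adjusted p = 0.0323), and both also passed over the list alone. With 1 array left out Lyz2 kept its call in 3 and Cd5l in 1 of 10 fits. Cd5l did not pass with equal array medians (limma adjusted p = 0.0707) or without controls 14 and 15 (limma adjusted p = 0.105), where Lyz2 did (limma adjusted p = 0.0367). Without controls 14 and 15 the list's median was 0.03 (camera adjusted p = 0.557). Targets of NRF2, the oxidative stress regulator, had 15 of 17 lower and a median of -0.18 (camera adjusted p = 0.0130), and adjusted p = 0.873 with an estimated correlation. Hmox1, heme oxygenase, was at -0.60 (SE 0.14, limma adjusted p = 0.0740), and was the only member that passed over the list alone. The camera adjusted p of this list was 0.159 without controls 14 and 15. It was 0.482 with the values as deposited, 0.489 with equal array medians, 0.576 with the further factor per array undone and 0.0511 with array weights.

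Hepatocyte secreted proteins and urea cycle genes passed as higher at the preset correlation, with 17 of 17 higher and a median of 0.08 (camera adjusted p = 0.0110). No member was past the threshold by either adjustment. With an estimated correlation the list's adjusted p was 0.873. Ass1, a urea cycle enzyme, was at 1.12 (SE 0.41, limma adjusted p = 0.220), and at 0.65 (SE 0.41, limma adjusted p = 0.525) without controls 14 and 15. Male-biased liver genes had 9 of 10 higher with a median of 0.56 (camera adjusted p = 0.0468), and adjusted p = 0.873 with an estimated correlation. Controls 14 and 15, the arrays with high Xist, were low in these genes, and without them the list turned lower, with a median of -0.44 (camera adjusted p = 0.00152), and adjusted p = 0.787 with an estimated correlation. C8a, a complement component, had the smallest p of the list, at 0.40 (SE 0.16, limma adjusted p = 0.256). Female-biased liver genes had 5 of 5 lower with a median of -0.28 (camera adjusted p = 0.498), and a median of 0.21 without controls 14 and 15. Prom1 was at -0.63 (SE 0.42).

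The other pathway lists did not pass with camera, though some of their members did. Circadian clock genes had 2 members higher and 1 lower among 16, with a camera adjusted p of 0.620. Camera tests for a shift in a shared direction, and these members moved both ways. Fry's mixed test, which ignores direction, gave this list an unadjusted p of 4.59e-08, the smallest of the lists tested. The next smallest unadjusted p of the mixed test was 9.29e-05, for endoplasmic reticulum stress. It was 0.000127 for endothelial markers, 0.000139 for lipid droplets, fatty acid uptake and lipolysis, and 0.000332 for the p53 and DNA damage response. A small mixed p was thus not particular to the clock list. Ciart rose by 0.84 (SE 0.17, limma adjusted p = 0.0435) and Nfil3 by 0.73 (SE 0.12, limma adjusted p = 0.0214), while Dbp fell by 0.44 (SE 0.08, limma adjusted p = 0.0323). None of the 16 passed over all genes without controls 14 and 15 (limma adjusted p = 0.0826 for Ciart, 0.0621 for Nfil3 and 0.0842 for Dbp). With 1 array left out Ciart kept its call in 1 and Nfil3 in 7 of 10 fits, and Ciart did not pass with equal array medians (limma adjusted p = 0.0912). Adjusted over the list alone, Nr1d1, a repressor of the clock, was lower as well, at -1.44 (SE 0.36). In glucose metabolism, Ppp1r3b, which targets protein phosphatase to glycogen, rose by 0.92 (SE 0.15, limma adjusted p = 0.0219) among 16 members, and did not pass without controls 14 and 15 (limma adjusted p = 0.0580). Adjusted over the list alone, Pck1, the gluconeogenic enzyme, was also higher at 0.43, and Pfkl, a phosphofructokinase, lower at -0.32 (camera adjusted p = 0.324). The list passed as higher with the values as deposited (camera adjusted p = 0.0167) and with equal array medians (camera adjusted p = 0.0483). With an estimated correlation and the main scaling its adjusted p was 0.873. In drug and xenobiotic metabolism Fmo5 rose by 0.37 (SE 0.07, limma adjusted p = 0.0311) and was the only one of 18 to pass by either adjustment (camera adjusted p = 0.851). Fmo5 did not pass as deposited (limma adjusted p = 0.126), with equal array medians (limma adjusted p = 0.110) or without controls 14 and 15 (limma adjusted p = 0.101), where Cyp2c55, at -0.67, was the only member past the threshold over all genes. Mx2 was the only interferon response gene of 25 to pass by either adjustment (camera adjusted p = 0.338). That list had a median of -0.06, and a median of 0.18 without controls 14 and 15 (camera adjusted p = 0.0474), and adjusted p = 0.964 with an estimated correlation. Without control 12 it passed in the opposite direction, as lower (camera adjusted p = 7.33e-05). With an estimated correlation over all arrays its adjusted p was 0.873. Manf, a protein of the endoplasmic reticulum stress response, fell by 0.54 (SE 0.08, limma adjusted p = 0.0114) among 21 members of that list (camera adjusted p = 0.145), of which 2 were lower and 1 higher adjusted over the list alone. This list passed as lower with the mean of probe sets (camera adjusted p = 0.0446) and without the _x_at and _s_at probe sets (camera adjusted p = 0.0212). With an estimated correlation and all probe sets its adjusted p was 0.873. Gadd45g was the only one of 18 genes of the p53 and DNA damage response to pass over all genes, with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.946). Gadd45g kept its call in 2 of 10 fits with 1 array left out. It did not pass without controls 14 and 15 (limma adjusted p = 0.0829).

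Markers of other cell types did not pass with camera, and none of their members passed over all genes. The camera adjusted p was 0.709 for T and NK cells, 0.577 for B and plasma cells, 0.671 for neutrophils, 0.577 for endothelial cells, 0.193 for stellate cells and matrix, 0.620 for bile duct and 0.768 for pancreatic acinar markers. The members with the smallest p were Cd8a at -0.72, Cd22 at 0.55, Mmp8 at 0.51, Fcgr2b at 0.28, Ngfr at -0.87, Krt19 at -0.89 and Cela1 at 0.26, in the order of the lists. The sign of Cd8a turned in 2 of 10 fits with 1 array left out. Its other probe sets, in part below the filter, gave -0.26, 0.24, 0.08 and 0.16. Ngfr was lower adjusted over the list alone, as 1 of 18 stellate cell and matrix genes. Only 2 red cell markers were tested, too few for camera, with Alas2 at 0.91 (SE 0.31, limma adjusted p = 0.181) and higher adjusted over the list alone. Alas2 was at 9.28 and 9.02 in controls 14 and 15 and at 10.05 or more in the other 8 arrays, and without these controls its log2 fold change was 0.34 (SE 0.16, limma adjusted p = 0.385).

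**Figure D3:**
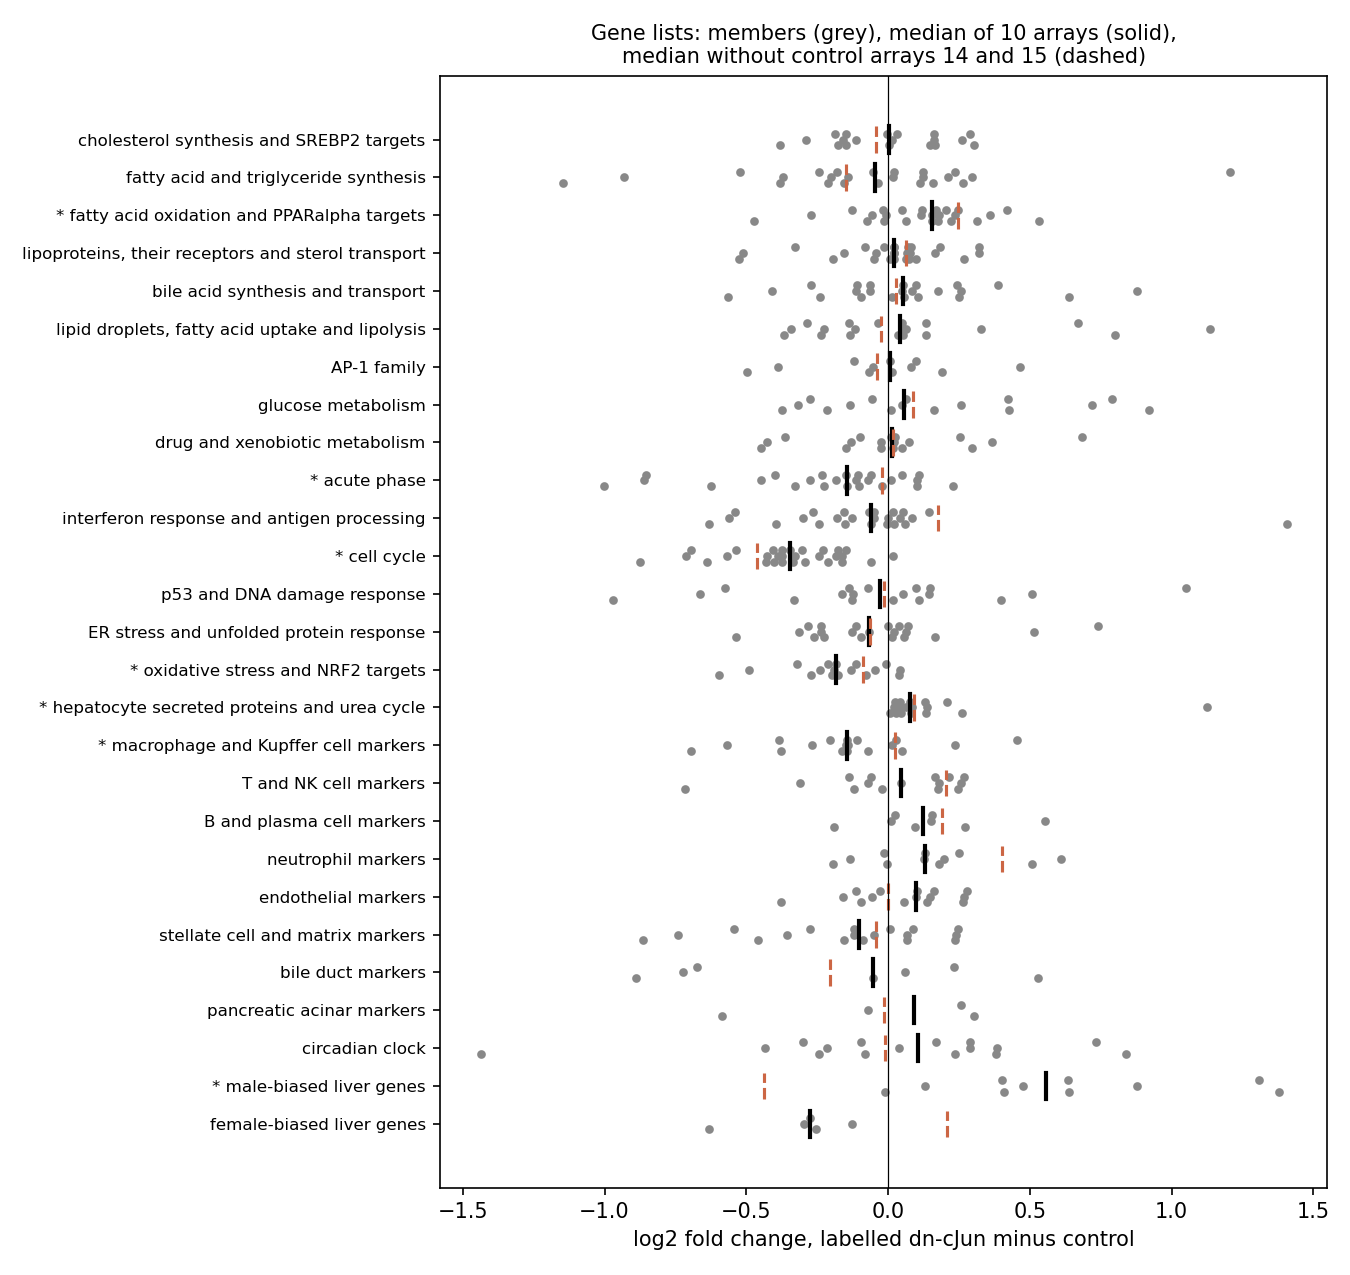
Log2 fold change (x axis, arrays labelled dn-cJun minus control) of each tested member of 27 gene lists (grey points), with the list's median over 10 arrays (solid line) and without controls 14 and 15 (dashed line); a star marks a camera adjusted p under 0.05 at the preset correlation. The cell cycle list is lower with and without these controls, at medians of -0.35 and -0.46, and the male-biased list changes sign, from 0.56 to -0.44.

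RNA quality as read by the control probe sets of Actb differed slightly between the groups. The log2 difference between its 3 prime and 5 prime probe sets was 0.40 ± 0.04 (SD, n = 5) in the control arrays and 0.52 ± 0.07 (SD, n = 5) in the arrays labelled dn-cJun. The difference of 0.12 had an exact permutation p of 0.00794, the smallest that 5 against 5 arrays can give (adjusted p = 0.0159). All 5 arrays labelled dn-cJun lay above all 5 controls. For Gapdh the values were -0.44 ± 0.03 and -0.47 ± 0.07 (SD, n = 5 each), a difference of -0.03 (exact permutation p = 0.405).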

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

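The split test of the gene count was planned before the data were examined, though its bound was written down after its result was seen, and the other tests weighed here were chosen after the results were seen.

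In 96 sets of 5 arrays, 7 held an array far from the other 4 by Dixon's ratio, against a limit of 0.71, and chance gives about 4.8 of 96. Control 12 was low in Hmox1 (10.19 against 10.73 to 10.92, ratio 0.750) and in Cd5l (13.05 against 13.45 to 13.56, ratio 0.787), and control 13 in Cd22 (6.52 against 6.98 to 7.08, ratio 0.814). Among the arrays labelled dn-cJun, array 20 was high in Cpne7 (7.71 against 7.42 to 7.49, ratio 0.758) and in its median log2 intensity as deposited (6.84 against 6.66 to 6.70, ratio 0.799). Array 17 was high in Mx2 (7.43 against 6.93 to 7.06, ratio 0.752), and array 19 low in Ngfr (6.03 against 6.96 to 7.22, ratio 0.781). Of 4175 probe sets without exactly 1 gene symbol, which no gene-level comparison uses, 23 passed the threshold in a fit over all 27022 probe sets above the filter, 10 higher and 13 lower. Their log2 fold changes reached 0.85 and -1.97.

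The first pattern weighed is the 42.6-fold higher Apoe signal in the arrays labelled dn-cJun. Scaling is argued against, since the log2 difference was at least 5.39 under 3 other scalings, and so is an exchange of single arrays between the groups, since the lowest array labelled dn-cJun lay 4.37 above the highest control. A chromosome segment around Apoe that differs between the groups cannot be told apart from none. Among the 100 nearest tested genes 16% had an unadjusted p under 0.05 against 14.9% elsewhere (odds ratio 1.09, Fisher's exact p = 0.777). The 20 nearest hold 1 gene past the threshold, Clasrp, and such a segment need not change the expression of its genes. Mice with an intact Apoe gene in that group, Apoe carried by the virus, and an effect of dn-cJun on a transcript left by the mutation remain open and untested, and each may account for the difference.

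The second pattern is the 99 genes past the threshold. Among 100 splits of the arrays into 5 and 5, 1 gave as many, the real one, and the highest other gave 5, so chance is excluded at that share. Controls 14 and 15, with the high Xist signal, are argued against as the source of all these calls: without them 52 genes passed, and of the 56 splits of the other 8 arrays into 3 and 5, 1 gave as many, the real one, and the highest other gave 3. Of the 99 genes 32 were among these 52. For the 67 that no longer passed, the part of controls 14 and 15 cannot be told apart from the loss of arrays: without other pairs of controls 12 to 68 of the 99 passed, and without 6 of these 9 pairs as few or fewer than 32, too few pairs to settle it. Gene by gene, their log2 fold changes kept a median of 0.98 of their size and their standard errors rose to a median of 1.18 of theirs. The median size of the fold change went from 0.585 to 0.512 and the median standard error from 0.114 to 0.127. In the calls lost without another pair the medians of the 2 ratios were 0.90 to 1.03 and 1.13 to 1.21. Genes chosen for a difference over all 10 arrays keep most of it whichever pair is left out, so the ratio of fold changes does not test the part of controls 14 and 15. A virus effect, a difference in Apoe genotype and a difference in RNA quality, as the Actb probe sets read it, follow the same groups. They remain open, untested by this design, as does any other difference between the groups that the labels do not give.

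The third pattern is the 7 lists past the threshold. Chance is not excluded for their number, since 42 of the 100 splits gave as many and the highest other gave 19, nor for the cell cycle list, where 7 of 100 splits, the real one included, gave a camera p as small as 4.44e-12 and the smallest other was 9.45e-16. All 6 others separated controls 14 and 15, and 5 of them held 4 of the 5 controls on one side. All 6 also kept controls 11 and 12 together, the arrays with the highest mean of the cell cycle genes (0.63 and 0.25). Other splits that kept controls 11 and 12 together gave a camera p of up to 0.18. Of the 41 other splits that kept controls 14 and 15 together none gave a p as small, and their smallest was 1.97e-11. Controls 14 and 15 are argued against as the source for 3 lists, whose median log2 difference without them was -0.46 (cell cycle), 0.24 (fatty acid oxidation) and 0.093 (hepatocyte secreted proteins and urea cycle). They may be the source for 3 others, where it was -0.021 (acute phase), 0.026 (macrophage and Kupffer cell markers) and -0.44 (male-biased genes). For NRF2 targets, with a median of -0.088 against -0.18, the part of these arrays cannot be told apart from the rest.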

How the results depend on the processing

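No paired analysis was possible because the groups share no replicate numbers. Alternatives with controls 14 and 15, with the further factor undone and with permuted list scores were chosen after seeing the data. The cause of a change was not tested unless stated. The counts of genes higher and lower, 44 and 55, became 22 and 468 as deposited, 16 and 28 with the mean of probe sets, 4 and 5 in eBayes without trend, 75 and 112 with every probe set as the unit (more tests), 3 and 5 at a threshold of 0.01, 120 and 130 at 0.1, and 8 and 8 with a minimum log2 fold change of 1. With equal array medians 20 were higher, with array weights 85 lower, without controls 14 and 15 13 higher, and with a term for them 95 lower. Leaving out 1 array gave 3 to 97 higher and 10 to 102 lower. In all, 55, 199, 41, 31 and 61 genes passed without control 11, 12, 13, 14 and 15, and 44, 13, 42, 16 and 20 without dn-cJun 16, 17, 18, 19 and 20. Of the 99 genes, 74 passed as deposited, 8 without trend and 57 with equal medians.

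Apoe kept its call under all 24 settings (log2 5.22 to 5.81, adjusted p at most 1.71e-05). The 26 called named genes lost their call in 177 of 611 fits. The 19 others gained a call in 11 of 449 fits. Jun ranged from -0.18 to 0.067 with 1 array left out and never passed. Cd8a was at 0.081 without the _x_at and _s_at probe sets and at -0.91 to 0.17 with 1 array left out. Prom1 was at 0.10 without controls 14 and 15 and at 0.11 with a term for them.

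Of 754 list tests under alternatives, 60 lost a call, 13 gained one and 3 reversed. Fatty acid oxidation lost its call with an estimated correlation (adjusted p = 0.873), with fry (0.674), with permuted scores (0.830) and without controls 14 and 15 with an estimated correlation (0.574), over a range of 5.82e-07 to 0.873. Lipoproteins passed as deposited (0.00924), with equal medians (0.0242) and with the factor undone (0.00632), over a range up to 0.992. Fatty acid and triglyceride synthesis passed without controls 14 and 15 (0.00368) and with a term for them (0.00375), over a range up to 0.873. The male-biased list turned lower without controls 14 and 15 (0.00152), with a term for them (0.00126) and without them with an estimated correlation (0.787). No list passed with an estimated correlation, fry's directional test (lowest adjusted p 0.4997) or permuted scores (lowest 0.321). Every fry value in this section is from the directional test, and fry's mixed test was not adjusted over the lists. For permuted scores the smallest exact p that 5 against 5 arrays can give is 0.00794. A list that reached it alone could not pass after adjustment over all lists, so this failure does not count against a single list. The lowest unadjusted exact permutation p was 0.0159 (cell cycle), followed by 0.0238 (acute phase). Without controls 14 and 15 these lists were at 0.0179, the smallest possible there, and 0.0893. With 1 array left out, the cell cycle and fatty acid oxidation lists kept their calls. Acute phase was lost without control 14 (0.151) or 15 (0.0899), macrophage markers without control 14 (0.113), 15 (0.0757) or dn-cJun 18 (0.0582), NRF2 targets without control 14 (0.113), dn-cJun 19 (0.221) or 20 (0.203), and hepatocyte genes without control 11 (0.194) or dn-cJun 20 (0.0762), and with array weights (0.0511). The male-biased list was lost without control 14 (0.382), 15 (0.634), dn-cJun 16 (0.104), 18 (0.0582), 19 (0.134) or 20 (0.0533), with a pseudocount of 64 (0.0599), at the 60th percentile filter (0.0803) and without trend (0.0900). Interferon genes passed as lower without control 12 (7.33e-05), and stellate cell and matrix genes as well (0.0228). The Actb difference in RNA quality kept its call, at 0.09 to 0.14, and that of Gapdh ranged from -0.060 (exact permutation p = 0.0159, without dn-cJun 20) to -0.013. Dim genes are limited by signal over background, which the pseudocount damps.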

Other observations

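The genes in this part were chosen after their values were seen. Controls 14 and 15 also stood apart from the other 8 arrays in genes known to differ between male and female mouse liver, in 9 of 10 male-biased and 4 of 5 female-biased genes tested. Cyp4a12a, a fatty acid hydroxylase of male liver, had log2 signals of 6.97 and 7.08 in these arrays and of 11.22 to 13.36 in the others. Elovl3, a fatty acid elongase, was at 7.72 and 8.32 against 10.78 to 12.76, and Hsd3b5, a steroid dehydrogenase, at 4.63 and 6.32 against 9.30 to 12.40. In the other direction, Hao2 was at 9.09 and 10.03 against 4.86 to 7.41, and Acot3, a peroxisomal thioesterase, at 12.20 and 12.43 against 8.55 to 10.89. The ranges of the 3 other controls and of the arrays labelled dn-cJun overlapped in Xist, Uty and 11 of these 15 genes, and were separate in the other 4. Elovl3 was at 12.51 to 12.76 in the 3 other controls and at 10.78 to 12.12 in the arrays labelled dn-cJun, C6, a complement component, at 12.84 to 13.17 and 11.94 to 12.51, Cyp2u1 at 8.71 to 9.07 and 7.93 to 8.57, and Hao2 at 4.86 to 6.45 and 6.89 to 7.41.

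Of the genes past the threshold outside the naming rule, 5 are given as examples. Insig2, which retains the SREBP complex in the endoplasmic reticulum, fell by 0.73 (SE 0.10, limma adjusted p = 0.00767), and by 0.88 without controls 14 and 15 (limma adjusted p = 0.000743). Alas1, the rate-limiting enzyme of hepatic heme synthesis, rose by 0.57 (limma adjusted p = 0.0228), and by 0.75 without these controls (limma adjusted p = 0.000931). Cebpb, a transcription factor of the liver, rose by 0.36 (limma adjusted p = 0.0274), and by 0.35 without these controls, where it did not pass (limma adjusted p = 0.0754). Tubb5, a tubulin, fell by 0.59 (limma adjusted p = 0.0179; 0.0418 without these controls), and Srf, a transcription factor of immediate early genes, rose by 0.65 (limma adjusted p = 0.0294) and did not pass without these controls (limma adjusted p = 0.0928).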
